A study of Mus musculus with 33 samples.

How the data were processed

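RNA was measured by sequencing in 33 libraries of sorted mouse brain cells, 6 with CSF1R inhibitor and 5 with vehicle in each of 3 populations: activated microglia, blood-derived phagocytes and resting microglia. Per the labels, cells were sorted by flow cytometry straight into lysis buffer, and their RNA was amplified with SMART-Seq v4, a kit that copies whole messenger RNA from very small inputs, using more PCR cycles where input was lowest. The labels do not give the cycles or cell number of single libraries, so neither could enter a fit. Libraries were made with Nextera XT and sequenced on a NextSeq, per the labels. The submitters' processing notes name bcl2fastq, without a version, and the genome build GRCm38. The aligner and the program that counted reads were not given in the sources used here.

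The first table deposited by the authors holds expected counts, estimates that can be fractions, for 21950 protein-coding genes, and 16.3% of all its values and 27.2% of those above 0 were not exactly equal to a whole number. They were rounded to whole numbers before the count models, which assume whole counts. The second table deposited by the authors holds log2 FPKM, log2 of fragments per kilobase of transcript and 1000000 fragments, with 1 added, for 27745 genes after a filter whose rule was not given; its 75th percentile was 2.936 in every library. Both tables share 17130 genes. Columns were matched to samples by the library name in the labels, and 0 columns were left unmatched. Gene symbols and GRCm38 positions came from the GENCODE M21 annotation, which named 21886 of the counted genes and left 64 without a symbol.

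Totals ran from 11789802 to 22146705 counts. The median library had 13399 genes with at least 1 count. No library fell under 0.7 times that median or under 1000000 counts, the limits set for leaving a library out, so none was left out of the main tests. With 3 counts as the floor, a group of 5 vehicle libraries could show a level of about 0.0322 CPM in activated and 0.0360 CPM in resting microglia.

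Counts were analysed in R 4.3.3 with edgeR 4.0.16. Each comparison used only the libraries of its groups. Genes were filtered with filterByExpr, libraries scaled by TMM, and groups compared with the robust quasi-likelihood F test. Genes under a Benjamini-Hochberg adjusted p of 0.05 were called, with no fold threshold. Inhibitor was compared with vehicle in each population, activated with resting microglia and blood-derived phagocytes with activated microglia in vehicle mice, and the inhibitor effect between each pair of populations as an interaction. Activated microglia of vehicle mice served in both vehicle comparisons, which are therefore not independent.

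Before the files were seen, 18 lists of functional themes and 11 lists of cell type markers were fixed, with 395 entries for 386 distinct genes, 3 of them entries for genes outside the count table. Themes were homeostatic microglia, disease-associated microglia, monocyte-derived cells, border-associated macrophages, type I interferon response, MHC class I and class II presentation, inflammatory mediators, phagocytosis and complement, lysosome, cell cycle, cholesterol biosynthesis, LXR targets and lipid efflux, CSF receptors and myeloid regulators, immediate early genes, glycolysis, oxidative phosphorylation, and p53 targets and apoptosis. Markers were of neutrophils, T, NK, B and dendritic cells, neurons, astrocytes, oligodendrocytes, endothelial cells, mural cells and fibroblasts, and erythroid cells. Lists with at least 3 measured members were tested with camera at a correlation of 0.01, again with an estimated correlation, and with fry, from limma 3.58.1, each adjusted over the lists of a comparison. The rule for naming genes was fixed at the same time. It takes up to 8 genes per direction with the smallest p among those past the threshold with a log2 fold change of at least 1 and a mean of at least 10 CPM, or 3 per direction if none passes, then up to 4 members per described list, and Csf1r, Ccr2, Ptprc and Itgam. Which lists to describe at length was chosen after the results were seen.

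Alternatives fixed beforehand were DESeq2 1.42.0, size factors by relative log expression (RLE), no filter beyond 1 count, all 33 libraries in 1 fit, limma-voom with quality weights, limma-trend on the authors' log2 FPKM, the number of detected genes as a covariate, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were sex as a covariate, leaving out the 3 activated microglia libraries with fewer than 11000 detected genes, neutrophil marker level as a covariate, and T and NK marker level as a covariate in blood-derived phagocytes. Genes found only in the log2 FPKM table were tested with limma-trend in the same fits as the log2 FPKM alternative, whose counts therefore include them. Every comparison was also repeated on 100 splits of the libraries, the real one included. The fitting code was tested on simulated data: of 100 genes changed by 1 log2 unit, the percentages recovered were 3 in activated microglia, 87 in blood-derived phagocytes and 84 in resting microglia for inhibitor against vehicle, 10 for activated against resting and 19 for blood-derived against activated cells, and 4 to 71 for the interactions, with 0 calls of wrong sign. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Small groups were compared with exact permutation tests, two-sided. Single-gene results for 3 genes are not reported here.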

Results

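The libraries came from brain cells of mice labelled as a cortical model of multiple sclerosis, given either a vehicle or an inhibitor of CSF1R, the receptor kinase on which microglia, the resident macrophages of the brain, depend for survival. Cells were sorted on surface proteins into 3 populations. Resting microglia had intermediate CD45 and CD11b. Activated microglia had high CD45 and CD11b without CCR2, the chemokine receptor of inflammatory monocytes. Blood-derived phagocytes had high CD45 and CD11b with CCR2. Each population had 6 inhibitor and 5 vehicle libraries, 33 in all. Libraries held 11789802 to 22146705 counts in protein-coding genes, and 9742 to 14861 genes had at least 1 count. Activated microglia varied most, with 12000 ± 1613 (SD) detected genes with inhibitor and 12070 ± 1300 with vehicle. The numbers were 14003 ± 373 and 14238 ± 438 in resting microglia and 13258 ± 392 and 13381 ± 148 in blood-derived phagocytes. Correlations between replicates of a group across genes ran from 0.662 to 0.950 in activated microglia, 0.964 to 0.985 in blood-derived phagocytes and 0.962 to 0.984 in resting microglia. The first axis of a principal component analysis held 47.9% of the variance and the second 17.1%.

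**Figure D1:**
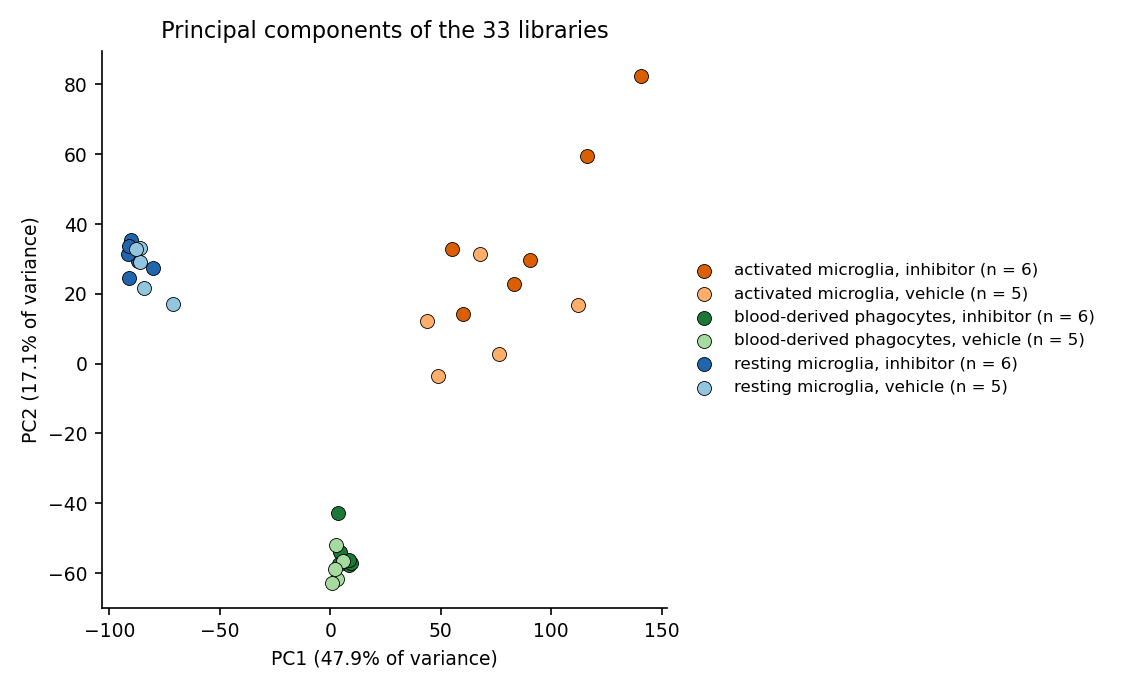
The 33 libraries on the first (47.9%) and second (17.1%) principal component of log2 CPM, each point 1 library coloured by population and treatment. The 3 populations lie apart, activated microglia are the most spread, and inhibitor and vehicle libraries of a population overlap.

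Levels are counts per 1000000 counts (CPM), means ± SD, and fold changes are log2 with standard error. Adjusted p-values for single genes come from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and "rose" or "fell" is used only under 0.05. For gene groups, camera compared the genes of a list with all other genes, at a preset correlation between genes of 0.01. Of all camera calls in the 8 comparisons, only the list of monocyte-derived cell genes in activated against resting microglia held when the correlation was estimated from the data. Of the 80 camera calls, 27 had a p that fewer than 5 of 100 splits of the libraries reached. Fry tests whether the genes of a list move on balance in 1 direction, without comparison with other genes. It passed for all 11 and all 15 lists that camera called in the vehicle comparisons, and elsewhere only where given. Counts of members adjusted over the list alone equalled those over all genes where none are given. The p-values measure only the spread between libraries, since the labels do not say whether libraries came from separate animals. Reads amplified by PCR without molecular barcodes are not independent molecules, so count intervals cover counting error only. The genes used for sorting or for the drug target were Csf1r (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149, GRCm38), Ccr2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557), Ptprc encoding CD45 (ENSMUSG00000026395, chromosome 1, 138062861 to 138175708) and Itgam encoding CD11b (ENSMUSG00000030786, chromosome 7, 128062640 to 128118491).

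Activated and resting microglia of vehicle mice, 5 libraries each, were compared to see what separates the gates in this model. Genes of blood cells were high in the activated gate, as given below. Lower levels of microglial genes there may reflect a mix of cells, a change of state or both, which the comparison cannot tell apart. Genes of resident microglia were much lower in the activated gate. Csf1r fell by 2.61 ± 0.30, 1760 ± 730 against 10739 ± 570 CPM (edgeR adjusted p = 8.0e-05). P2ry12, a nucleotide receptor gene chosen after its values were seen, stood at 198 ± 176 CPM against 2619 ± 620 CPM. Of 16 homeostatic microglia genes 15 fell, and 16 fell when adjusted over the list alone (median -3.14; camera adjusted p = 1.8e-10, adjusted p = 0.308 with an estimated correlation). Examples were P2ry13 (-2.30), Cst3 (-2.08), Tgfbr1 (-2.19) and Cx3cr1 (-2.64), which encode another nucleotide receptor, a protease inhibitor, a TGF-beta receptor and the fractalkine receptor. Ptprc rose by 1.27 ± 0.19 and Ccr2 rose by 3.69 ± 0.76, 94.5 ± 56.2 against 7.29 ± 7.28 CPM, while Itgam fell (-0.68 ± 0.22, edgeR adjusted p = 0.0393). The Itgam call was lost in 5 of 10 fits with 1 library left out, those without vehicle activated microglia replicate 1 or 3 or vehicle resting microglia replicate 1, 2 or 3.

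Genes of infiltrating blood cells were far higher in the activated gate. Of 17 monocyte-derived cell genes 16 rose, and 17 when adjusted over the list alone (median 4.44; camera adjusted p = 2.0e-26, adjusted p = 0.00445 with an estimated correlation). They included Ccr1 (4.37), S100a6 (8.57), Cd44 (4.39) and Plac8 (4.44), a chemokine receptor, a calcium-binding protein, a hyaluronan receptor and a placenta-associated gene of myeloid cells. All 11 neutrophil genes rose (median 9.86; camera adjusted p = 7.3e-11, adjusted p = 0.252 with an estimated correlation). Cxcr2, the neutrophil chemokine receptor, stood at 1135 ± 358 against 0.387 ± 0.482 CPM, Ly6g rose by 10.16 and Mmp9 by 10.44. All 7 natural killer (NK) cell genes tested rose (median 9.66; camera adjusted p = 1.8e-10, adjusted p = 0.155 with an estimated correlation), among them the granzymes Gzmb (9.66) and Gzma (10.78) and the receptor Ncr1 (10.03). All 8 T cell genes tested rose (median 6.09; camera adjusted p = 3.0e-08, adjusted p = 0.155 with an estimated correlation), for example Lck (6.51), Cd28 (5.67) and Cd3e (6.04). Of 5 B cell genes tested 3 rose (median 7.38; camera adjusted p = 0.0103, adjusted p = 0.365 with an estimated correlation), a call that held in 6 of 7 other settings of the fit. The NK and B cell medians were the same with members without a count in resting microglia set at their lower bound. Neutrophil genes took 4.38 ± 2.44% of all counts in vehicle activated microglia, against 0.0929 ± 0.0104% in resting microglia and 0.0488 ± 0.00860% in blood-derived phagocytes.

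**Figure D2:**
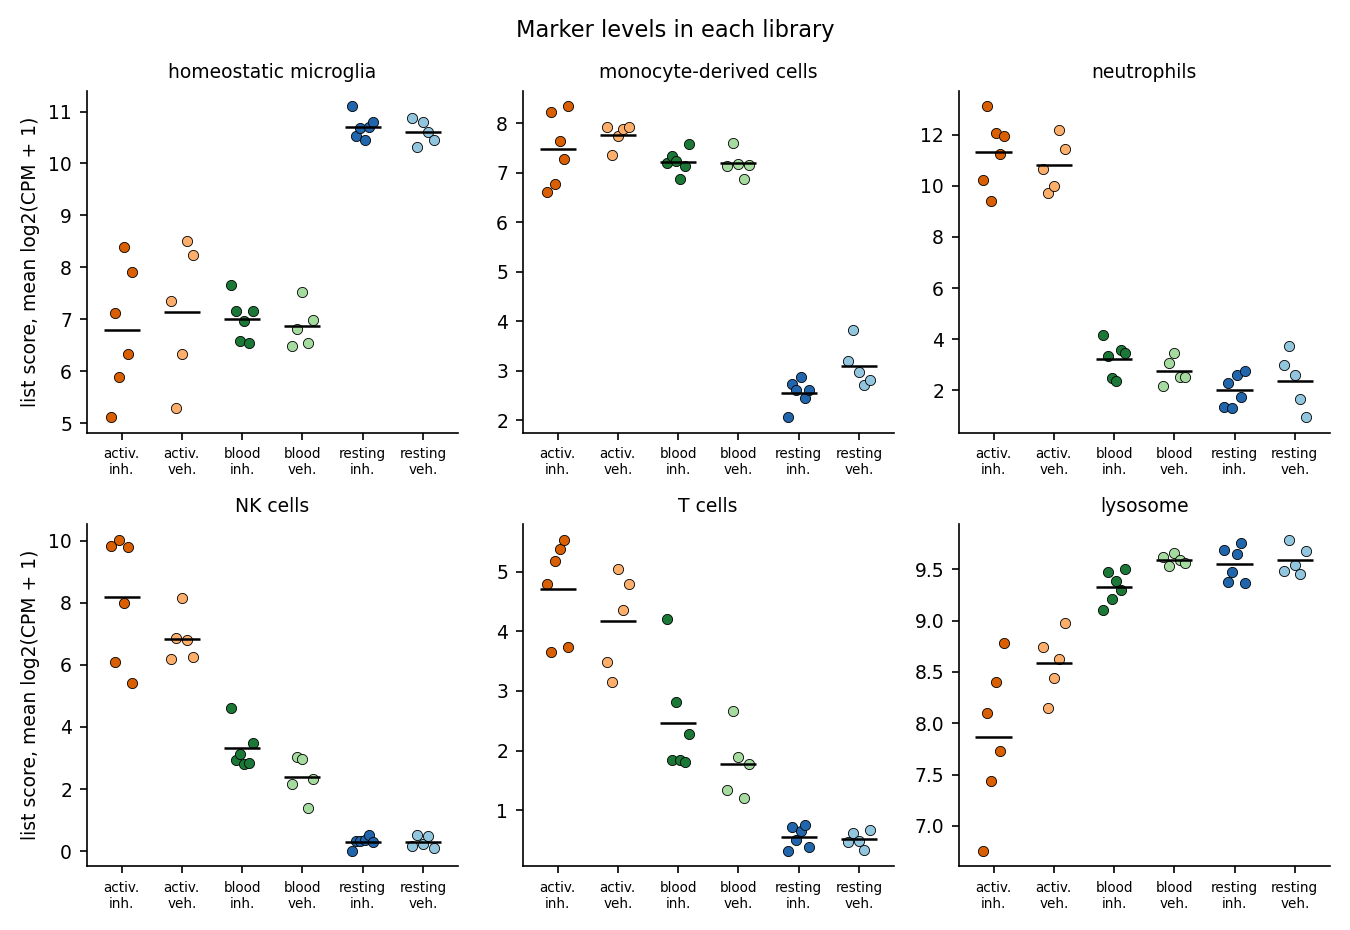
List scores, the mean log2 of CPM with an offset of 1, of 6 gene lists, each point 1 of the 33 libraries and each bar a group mean; axes differ between panels and do not start at 0. The neutrophil, NK and T cell scores are highest in the activated microglia gate, where neutrophil genes took 4.38% of counts with vehicle.

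For the lists that follow, a mix of cells in the activated gate and a change of state cannot be told apart either. Interferon-response genes were higher beside the blood cell genes. Of 21 members 13 rose, 15 adjusted over the list alone (median 1.34; camera adjusted p = 6.5e-07, adjusted p = 0.365 with an estimated correlation), with Rsad2 (3.68), Isg15 (3.19), Ifit1 (2.35) and Oasl2 (3.02). Glycolysis genes rose in 9 of 12 and fell in 1 (median 1.19; camera adjusted p = 1.2e-05, adjusted p = 0.252 with an estimated correlation), including the enolase gene Eno1 (1.65) and the phosphofructokinase gene Pfkp (3.53). Lysosome genes went the other way, with 16 of 22 lower, 1 higher and 17 lower adjusted over the list alone (median -1.07; camera adjusted p = 5.0e-06, adjusted p = 0.365 with an estimated correlation). Lower members included Grn (-1.65), Gaa (-1.64) and Hexa (-1.57), which encode progranulin and lysosomal glycosidases. Phagocytosis and complement genes fell in 11 of 22 and rose in 4, 12 and 5 adjusted over the list alone (median -0.94; camera adjusted p = 0.00765, adjusted p = 0.70 with an estimated correlation), among them Fcgr1 (-1.76), Pros1 (-3.33) and C1qb (-1.99). In 7 other settings of the fit medians ran from -1.02 to -0.11 for phagocytosis, from -1.14 to -0.69 for lysosome and from -3.51 to -1.80 for homeostatic microglia genes. Targets of p53 rose in 9 of 13 (median 1.03; camera adjusted p = 6.0e-04, adjusted p = 0.252 with an estimated correlation). The disease-associated microglia list did not pass, with 6 of 20 genes higher and 5 lower, 7 and 7 adjusted over the list alone (median 0.36, camera adjusted p = 0.387), although it passed at adjusted p = 0.0498 without vehicle resting microglia replicate 2. Of its genes Ccl6 (2.75), Lgals3 (3.75) and Lyz2 (3.65) rose and the lipid receptor gene Trem2 (-2.19) fell. Inflammatory mediators rose in 6 and fell in 6 of 21, 8 and 7 adjusted over the list alone (camera adjusted p = 0.905), from Cxcl2 (5.88) and Il1b (4.54) to Ccl4 (-1.57) and Ccl2 (-1.55). Their median was -0.23 and their mean 0.43. The median also differed in sign from the test for the LXR target and neuron lists. The other lists had camera adjusted p between 0.182 and 0.952.

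In all, 3499 of 12098 genes tested differed, 2205 higher and 1294 lower, and 2434 of them by at least 1 log2 unit. The smallest p among genes higher in the activated gate belonged to Smpdl3a, a sphingomyelinase-like gene (ENSMUSG00000019872, chromosome 10, 57794335 to 57811830; 2.56 ± 0.12, 266 ± 27.7 against 45.0 ± 0.801 CPM, edgeR adjusted p = 1.5e-06). It was followed by Prdx6 (3.02), Hdc (9.91), Ezr (4.35), Chil1 (6.92), Emb (5.75), Ifitm1 (8.91) and Gsr (5.34), which include antioxidant enzymes, the histamine-forming enzyme and an interferon-induced membrane protein. Among lower genes came Pde4dip, a centrosomal anchor (ENSMUSG00000038170, chromosome 3, 97689824 to 97888707; -2.38 ± 0.16, edgeR adjusted p = 4.1e-06), then F11r (-2.12), Bicd2 (-1.35), Nrip1 (-1.92), Tlr3 (-3.46), Fez2 (-1.78) and Gna15 (-1.97). The basement membrane gene Nid2, summed over libraries, had 1 count in activated and 1593 in resting microglia, a ratio of 1778 with a 95% counting interval of 319 to 70279. This interval leaves out the spread between libraries. Genes whose 2 groups did not overlap made up 33% of those tested, against 0.794% by chance. Without vehicle activated microglia replicate 2, the library of this group with the fewest detected genes, 5103 genes differed. The split moved to 2621 higher and 2401 lower with limma-voom, and to 2348 and 2384 with the authors' log2 FPKM.

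Blood-derived phagocytes were compared with activated microglia of vehicle mice, 5 libraries each, to see how the 2 sorted phagocyte gates differ. Neutrophil genes took 4.38 ± 2.44% of counts in the activated gate and 0.0488 ± 0.00860% in the blood-derived gate. For all lists and genes of this comparison, a different mix of cells and a difference between the phagocytes therefore cannot be told apart. The lysosome, LXR target and MHC class II lists were higher in the blood-derived gate by camera. Of 22 lysosome genes 17 rose (median 1.02; camera adjusted p = 1.1e-13, adjusted p = 0.128 with an estimated correlation). First came Psap, the saposin precursor (ENSMUSG00000004207, chromosome 10, 60277627 to 60302597), at 13410 ± 749 against 3434 ± 608 CPM (1.97 ± 0.14, edgeR adjusted p = 8.9e-06), and then Ctsb (1.82), Hexa (1.84), Grn (1.53) and Lamp1 (1.35). Targets of LXR, the sterol-sensing receptor, rose in 4 of 10 (median 0.47; camera adjusted p = 0.00480, adjusted p = 0.128 with an estimated correlation). These were the lipid carriers Pltp (2.42) and Apoe (1.68), the cholesterol exporter Abca1 (1.47) and the receptor itself, Nr1h3 (2.01). Apoe stood at 38887 ± 5850 against 12129 ± 5825 CPM. Adjusted over the list alone 5 LXR targets and 6 MHC class II genes rose, 1 lysosome gene and 5 disease-associated microglia genes fell. MHC class II genes rose in 4 of 8 (median 0.83; camera adjusted p = 0.0132, adjusted p = 0.493 with an estimated correlation), namely H2-Aa (1.03), H2-Ab1 (0.99), H2-DMa (0.84) and H2-DMb1 (0.82). Phagocytosis and complement genes rose in 6 of 22, and adjusted over the list alone 8 rose and 1 fell (median 0.72; camera adjusted p = 0.00164, adjusted p = 0.407 with an estimated correlation), including the scavenger receptor Msr1 (1.99) and C3ar1 (1.82). Disease-associated microglia genes rose in 10 and fell in 4 of 20 (median 0.54; camera adjusted p = 0.0306, adjusted p = 0.493 with an estimated correlation). Of these Cd68 (1.41) and Trem2 (1.48) were higher and Csf1 (-4.71) and Ccl6 (-2.16) were lower. Csf1r rose by 1.17 ± 0.26 and Ccr2 by 1.24 ± 0.32 (213 ± 21.7 against 90.4 ± 52.6 CPM). Ptprc fell by 0.91 ± 0.15, and Itgam at -0.40 ± 0.19 did not pass (edgeR adjusted p = 0.185). The homeostatic microglia list did not pass between these gates (camera adjusted p = 0.492).

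Neutrophil, NK and T cell genes were lower in the blood-derived gate beside these changes. All 11 neutrophil genes fell (median -9.13; camera adjusted p = 1.6e-34, adjusted p = 0.0556 with an estimated correlation), for example Cxcr2 (-11.42), Mmp9 (-10.50) and S100a9 (-10.60). NK cell genes fell in 7 of 8 (median -5.40; camera adjusted p = 1.7e-11, adjusted p = 0.128 with an estimated correlation). T cell genes fell in 9 of 11 (median -2.91; camera adjusted p = 2.9e-05, adjusted p = 0.217 with an estimated correlation) and B cell genes in 3 of 5 (median -7.77; camera adjusted p = 0.00164, adjusted p = 0.176 with an estimated correlation). Among them were Gzma (-5.90), Klrb1c (-5.22) and Lck (-3.85). Of 18 monocyte-derived cell genes 3 rose and 7 fell (median -0.29; camera adjusted p = 0.00499, adjusted p = 0.165 with an estimated correlation), the falls including S100a6 (-3.13), Ccr1 (-2.21) and Hp (-4.22). Ly6c2, a surface protein of inflammatory monocytes, had 794 ± 552 CPM in blood-derived and 653 ± 220 CPM in activated cells. Interferon-response genes fell in 6 of 21 and rose in 1 (median -0.59; camera adjusted p = 0.00341, adjusted p = 0.493 with an estimated correlation), with Rsad2 (-2.20) and Isg15 (-2.70). The colony-stimulating factor and myeloid regulator list had 3 higher and 7 lower of 14 (median -0.63; camera adjusted p = 0.0284, adjusted p = 0.165 with an estimated correlation), including Cebpb (-1.64). Inflammatory mediators had 1 higher and 6 lower of 21 (median -0.57; camera adjusted p = 0.0353, adjusted p = 0.165 with an estimated correlation). Cell cycle genes fell in 5 of 25 (median -1.32; camera adjusted p = 0.00499, adjusted p = 0.493 with an estimated correlation) and p53 targets in 4 of 12 (median -0.68; camera adjusted p = 0.00499, adjusted p = 0.165 with an estimated correlation). Adjusted over the list alone the numbers lower became 8 for NK cells, 10 for T cells, 4 for B cells, 8 for monocyte-derived cells with 4 higher, 10 for interferon response, 8 for colony-stimulating factors, 6 for cell cycle and 8 for p53. Median and test differed in sign in 5 lists that did not pass, whose camera adjusted p ran from 0.0682 to 0.893 with the rest.

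Of 11598 genes 2176 differed, 751 higher and 1425 lower in blood-derived phagocytes, 1339 of them by at least 1 log2 unit. G0s2, a lipase inhibitor abundant in neutrophils (ENSMUSG00000009633, chromosome 1, 193272161 to 193273217), fell by 11.13 ± 0.44 (edgeR adjusted p = 3.7e-07), ahead of Hdc (-9.01), Retnlg (-12.79), Ripor2 (-4.46), Cebpd (-2.43), Lrg1 (-6.96), Steap4 (-8.64) and Il1f9 (-10.26). Higher genes besides those above were the transporter Abcc3 (1.80), the chaperone Canx (1.07), Vwa5a (1.25) and Uap1l1 (1.58). Non-overlapping genes made up 22.0% against 0.794% by chance. Without vehicle activated microglia replicate 2 the count was 3619, and the calls of the disease-associated microglia (adjusted p = 0.0765), MHC class II (0.0694) and colony-stimulating factor lists (0.0934) ended. The disease-associated microglia call also ended without vehicle activated microglia replicate 1 (0.138), 3 (0.0693) or 4 (0.0552). H2-Ab1, H2-DMa and H2-DMb1 each lost their call in 3 to 5 of 10 such fits, and the inflammatory mediator call held in 8. In 7 other settings of the fit, the colony-stimulating factor call held in 3, disease-associated microglia and inflammatory mediators in 4 each, MHC class II in 5, and LXR targets and p53 targets in 6 each. Medians there ran from -2.15 to -0.83 for cell cycle genes, 0.13 to 0.83 for phagocytosis genes, 0.46 to 1.09 for LXR targets and -0.69 to -0.45 for p53 targets. Without vehicle activated microglia replicate 5 the medians of LXR targets and disease-associated microglia genes were 1.11 and 0.91. That of monocyte-derived cell genes was -0.16 without replicate 3 of that group and that of phagocytosis genes 0.42 without replicate 2. With the authors' log2 FPKM the median of all genes shifted by 0.18 and the split became 1733 higher and 1483 lower; with limma-voom the median shifted by 0.12.

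In blood-derived phagocytes, inhibitor (n = 6) was compared with vehicle (n = 5) to see what the drug changed in cells that had entered from the blood. A set of 32 genes changed, 26 higher and 6 lower, mostly by less than 1 log2 unit. The 4 that rose by at least 1 log2 unit included Dnajb13, a co-chaperone gene (ENSMUSG00000030708, chromosome 7, 100501716 to 100514960), at 13.4 ± 4.79 against 5.31 ± 0.326 CPM (1.33 ± 0.22, edgeR adjusted p = 0.0231). The next was Traf1, an adaptor of tumour necrosis factor receptors (ENSMUSG00000026875, chromosome 2, 34941750 to 34961772), at 75.2 ± 24.3 against 34.6 ± 6.09 CPM (1.12 ± 0.20, edgeR adjusted p = 0.0410). The other two were Il18rap (1.76), an interleukin-18 receptor chain whose mean stayed under the 10 CPM of the naming rule, and the clone-named gene D130040H23Rik (1.5); both were chosen after their values were seen. So were 4 others that rose, Clk1 (0.64), Ccnl1 (0.73), Top1 (0.66) and Srsf5 (0.58), and the cell cycle inhibitor Cdkn1b (0.82). Among the 6 that fell were the survival gene Bcl2l1 (-0.59), the small GTPase gene Rab32 (-0.48), Lrp12 (-0.82), Ppfibp1 (-0.86) and Itpripl2 (-0.49). Csf1r, at -0.09 ± 0.10, did not pass (edgeR adjusted p = 0.746), and neither did Ccr2 (0.19), Ptprc (0.18) and Itgam (-0.13).

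Lysosome and phagocytosis genes were lower with inhibitor as groups. In the same libraries genes outside the protein-coding table were higher by 0.239 log2 FPKM relative to genes in it (exact permutation p = 0.00866), and whether this underlies the list changes was not tested. Phagocytosis and complement genes had 22 of 22 lower (median -0.29; camera adjusted p = 1.8e-08, adjusted p = 0.231 with an estimated correlation). None fell over all genes, 9 fell when adjusted over the list alone, and fry gave adjusted p = 0.0260. Lysosome genes had 21 of 22 lower (median -0.25; camera adjusted p = 1.4e-10, adjusted p = 0.352 with an estimated correlation). Of these 1 fell, and adjusted over the list alone 12 fell and 1 rose. Members were Ctsb (-0.62), Hexa (-0.53), Grn (-0.50), Itgb2 (-0.29), C1qc (-0.31) and C1qb (-0.30), none past the threshold, encoding a cathepsin, a hexosaminidase, progranulin, an integrin chain and complement chains. The disease-associated microglia list had 18 of 20 lower (median -0.31; camera adjusted p = 1.2e-06, adjusted p = 0.352 with an estimated correlation). Of these 4 fell when adjusted over the list alone, and members included Fabp5 (-0.67), Lgals3 (-0.47) and Cd68 (-0.34). LXR targets had 9 of 10 lower (median -0.23; camera adjusted p = 0.00258, adjusted p = 0.352 with an estimated correlation). Adjusted over the list alone 2 fell, and members included Abcg1 (-0.29) and Scd2 (-0.42). The LXR call ended with T and NK marker level as a covariate (median -0.09, adjusted p = 0.103), and the median was -0.15 without vehicle replicate 3.

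Immediate early genes, which respond within minutes to stimuli, were higher, with 19 of 19 higher (median 0.35; camera adjusted p = 1.4e-07, adjusted p = 0.413 with an estimated correlation). Of these Ier2 rose (0.68 ± 0.12, 569 ± 67.2 against 354 ± 61.2 CPM), 4 rose adjusted over the list alone, and Egr1 (0.82), Junb (0.48) and Egr3 (0.71) did not pass over all genes. Dendritic cell genes had 7 of 7 higher (median 1.02; camera adjusted p = 1.4e-04, adjusted p = 0.352 with an estimated correlation). Again 4 rose when adjusted over the list alone, and members included Flt3 (1.35), Cd209a (1.55), Clec9a (1.26) and Zbtb46 (1.02). Cd209a stood at 210 ± 85.7 against 71.8 ± 34.9 CPM. NK cell genes had 8 of 8 higher (median 1.19; camera adjusted p = 1.9e-04, adjusted p = 0.413 with an estimated correlation). T cell genes had 11 of 11 higher (median 1.35; camera adjusted p = 0.00267, adjusted p = 0.581 with an estimated correlation). Members included Gzma (1.19), Ncr1 (1.18), Cd3d (1.72), Cd2 (1.71), Cd5 (1.00) and Cd4 (0.68). No dendritic, NK or T cell gene passed over all genes. With T and NK marker level as a covariate, chosen after the data were seen, the calls of the dendritic cell (median 0.20, adjusted p = 0.0553), NK cell (0.19, adjusted p = 0.183) and T cell lists (-0.27, adjusted p = 0.305) ended, the last pair by construction of the covariate. NK cell genes took 0.0128 ± 0.00883% of counts with inhibitor and 0.00637 ± 0.00224% with vehicle. MHC class II genes had 8 of 8 higher (median 0.25; camera adjusted p = 0.00839, adjusted p = 0.581 with an estimated correlation). The cell cycle list had 22 of 25 lower (median -0.30; camera adjusted p = 0.00359, adjusted p = 0.615 with an estimated correlation). The oligodendrocyte list had 5 of 5 lower (median -0.52; camera adjusted p = 0.0224, adjusted p = 0.413 with an estimated correlation), and the MHC class I list 8 of 9 lower (median -0.12; camera adjusted p = 0.0407, adjusted p = 0.615 with an estimated correlation). With 1 library left out the MHC class I call held in 7 of 11 fits and those of MHC class II, cell cycle and oligodendrocyte genes in 10 each, and MHC class I held in 6 of 7 other settings of the fit. Inhibitor replicate 1 carried much of the immune cell lists. Without it the medians were 0.36 for T cell (adjusted p = 0.0465), 0.64 for NK cell and 0.58 for dendritic cell genes. The cell cycle median was -0.045 without vehicle replicate 1 (adjusted p = 0.429) and -0.46 without vehicle replicate 5. Immediate early genes had 0.20 and 0.21 without vehicle replicates 2 and 4, MHC class II 0.14 without inhibitor replicate 3 (adjusted p = 0.0750) and oligodendrocyte genes -0.35 without vehicle replicate 3 (adjusted p = 0.176). The MHC class I median ran from -0.22 to -0.03 in these fits, and in other settings oligodendrocyte genes ran from -1.13 to -0.51 and immediate early genes from 0.32 to 0.54. The other lists had camera adjusted p between 0.0729 and 0.876.

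**Figure D3:**
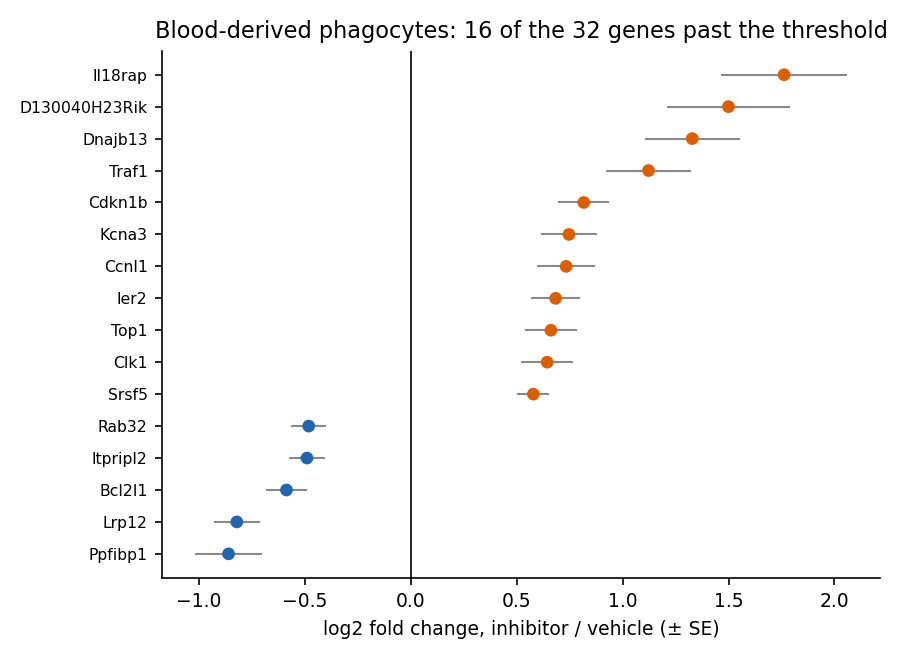
Log2 fold change, inhibitor against vehicle, of the 16 genes named in the text among the 32 past the threshold in blood-derived phagocytes, with bars for the standard error of the fit. Of those drawn 11 lie above 0 and 5 below.

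The 32 calls were made among 11670 genes, of which 1702 had an unadjusted p under 0.05, where 584 are due by chance. Non-overlapping genes made up 2.18% against 0.433% by chance. The count depended on single libraries. It fell to 0 without inhibitor replicate 5, 3 without inhibitor replicate 3, and 2 without vehicle replicate 1 or 3. It was 8 without vehicle replicate 2, 10 without vehicle replicate 4, 16 without vehicle replicate 5 and 19 without inhibitor replicate 2, and rose to 181 without inhibitor replicate 6. DESeq2 called 342 (216 higher, 126 lower), limma-voom 142 (96 and 46) and limma-trend on the authors' log2 FPKM 133 (90 and 43). Dnajb13, Traf1 and Ier2 each lost their call in 6 to 8 of the 11 fits without 1 library, and all with T and NK marker level as a covariate, where no gene was called.

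In activated microglia, inhibitor (n = 6) and vehicle (n = 5) were compared with the same question. No gene passed: 0 of 11675 were called by edgeR, and 417 had an unadjusted p under 0.05, where 584 are due by chance. DESeq2 called 1, Il18rap, limma-voom 0 and limma-trend on log2 FPKM 0, and edgeR on all 33 libraries together called 322. Without the 3 activated microglia libraries that had the fewest detected genes, 0 were called. The spread between these libraries was large, with a biological coefficient of variation of 0.946 against 0.242 in blood-derived phagocytes and 0.265 in resting microglia, and in simulated data with this spread 26% of genes changed by 2 log2 units were recovered. The genes with the smallest p were Il18rap, 298 ± 82.7 against 123 ± 32.1 CPM (1.28 ± 0.26), and the ubiquitin ligase gene Nedd4, 63.1 ± 18.0 against 20.9 ± 8.60 CPM, on the higher side. On the lower side were Cd302 (-1.35), Creb5 (-2.27) and Npc2 (-1.05), all with edgeR adjusted p = 0.999. The centromere gene Cenph, summed over libraries, had 727 counts with inhibitor and 2 with vehicle, a ratio of 284 with a 95% counting interval of 78.2 to 2346. This interval leaves out the large spread between libraries, and Cenph did not pass. Csf1r was at 1026 ± 795 against 1616 ± 619 CPM (-0.66 ± 0.51), with Ptprc (0.56), Ccr2 (-1.18) and Itgam (0.36).

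Several groups shifted together. LXR targets had 10 of 10 lower (median -1.07; camera adjusted p = 1.2e-06, adjusted p = 0.0595 with an estimated correlation). A total of 3 fell when adjusted over the list alone, and fry gave adjusted p = 0.0401. Examples were Abca1 (-1.16), Abcg1 (-0.98) and Pltp (-0.98), with Abca1 at 94.1 ± 51.2 against 210 ± 72.2 CPM. Lysosome genes had 20 of 22 lower (median -0.55; camera adjusted p = 1.9e-09, adjusted p = 0.346 with an estimated correlation), 1 of them past the threshold adjusted over the list alone. Members included Lamp1 (-0.88) and Gusb (-0.73). The disease-associated microglia list had 16 of 20 lower (median -0.56; camera adjusted p = 3.8e-06, adjusted p = 0.346 with an estimated correlation). Members included Apoe (-1.51), Ctsb (-0.95) and Fabp5 (-0.85). Apoe stood at 4151 ± 3424 against 11805 ± 5680 CPM. Phagocytosis and complement genes had 17 of 23 lower (median -0.79; camera adjusted p = 0.00128, adjusted p = 0.528 with an estimated correlation). Members included C3ar1 (-1.28), Itgav (-1.02) and Cd68 (-0.99). Inflammatory mediators had 15 of 20 lower (median -0.40; camera adjusted p = 8.6e-04, adjusted p = 0.205 with an estimated correlation). Members included Ccl2 (-1.20), Il1a (-1.20) and Ccl5 (2.25). Cell cycle genes had 24 of 25 higher (median 0.97; camera adjusted p = 3.7e-09, adjusted p = 0.346 with an estimated correlation). Members included Birc5 (1.32), Top2a (0.95), Ube2c (1.46) and Tyms (1.41). Without vehicle replicate 5 the phagocytosis median was -0.39, and without inhibitor replicate 3 the inflammatory median was -0.25. In other settings of the fit, medians ran from -0.98 to -0.57 for disease-associated microglia, -0.85 to -0.53 for lysosome and -0.67 to -0.40 for inflammatory genes.

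Markers of other cells moved with the same comparison. NK cell genes had 8 of 8 higher (median 2.08; camera adjusted p = 1.1e-06, adjusted p = 0.349 with an estimated correlation). In this list 7 rose when adjusted over the list alone, and members included Klrb1c (2.29), Gzma (2.23) and Nkg7 (2.14). The list took 0.747 ± 0.695% of counts with inhibitor against 0.170 ± 0.122% with vehicle. Inhibitor replicates 1, 3 and 5 had the highest NK cell scores of their group (9.82, 10.03 and 9.79) and the lowest lysosome scores (6.76, 7.44 and 7.73). No T and NK marker covariate was run here. A changed mix of cells and a response of microglia therefore cannot be told apart for the lists above. Neutrophil genes had 11 of 11 higher (median 0.73; camera adjusted p = 0.0126, adjusted p = 0.636 with an estimated correlation). Members included Ly6g (0.89), S100a9 (0.78) and Camp (1.10), and the list took 6.5 ± 4.34% against 4.38 ± 2.44% of counts. That call ended without inhibitor replicate 2 (adjusted p = 0.506), 4 (0.0632) or 6 (0.0624) or vehicle replicate 1 (0.0627) or 3 (0.124). T cell genes had 9 of 11 higher (median 0.92; camera adjusted p = 0.0295, adjusted p = 0.528 with an estimated correlation), a call that held in 5 of 11 fits with 1 library left out. The interferon-response list had 17 of 21 higher (median 0.33; camera adjusted p = 0.00736, adjusted p = 0.547 with an estimated correlation). The border-associated macrophage list had 8 of 10 lower (median -0.99; camera adjusted p = 0.00802, adjusted p = 0.528 with an estimated correlation), and MHC class II 7 of 8 lower (median -0.57; camera adjusted p = 0.00802, adjusted p = 0.547 with an estimated correlation). These calls held in 8, 10 and 10 of 11 fits with 1 library left out, and in 5, 7 and 5 of 8 other settings, in which T cell genes held in 6. Neutrophil genes held in 4 of the 7 that do not use their own level as a covariate. Without inhibitor replicate 2 the neutrophil and interferon medians were 0.12 and 0.18 (adjusted p = 0.170 for the latter), and without vehicle replicate 1 the MHC class II median was -0.34 (adjusted p = 0.168). The T cell median was 0.59 without vehicle replicate 2, the neutrophil median 1.14 without vehicle replicate 4 and the macrophage median -1.61 without inhibitor replicate 6. Across the same settings medians ran from 0.13 to 0.74 for neutrophil, 1.14 to 2.10 for NK cell, 0.56 to 1.19 for T cell, 0.12 to 0.33 for interferon and -1.63 to -1.004 for border-associated macrophage genes. The mean differed in sign from the test in 4 lists that did not pass, and the lists outside the calls had camera adjusted p between 0.122 and 0.957.

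In resting microglia, inhibitor (n = 6) and vehicle (n = 5) were compared to see how the drug changed the cells that stayed in the resting gate. No single gene passed over all genes, and Csf1r stood at 11863 ± 1106 against 11284 ± 599 CPM (0.07 ± 0.11). Cell cycle genes were lower as a group, with 25 of 25 lower (median -0.81; camera adjusted p = 2.5e-29, adjusted p = 0.168 with an estimated correlation). When adjusted over the list alone 11 fell. The spindle gene Tpx2 was at 10.6 ± 4.36 against 23.4 ± 4.56 CPM (-1.14 ± 0.25), and Bub1 (-1.47), Rrm2 (-1.25) and Cdk1 (-0.77) were likewise lower without passing. Monocyte-derived cell genes had 15 of 15 lower (median -0.62; camera adjusted p = 4.6e-09, adjusted p = 0.168 with an estimated correlation), 1 of them past the threshold adjusted over the list alone. Members included Ly6c2 (-1.68), Chil3 (-2.38), S100a6 (-1.36) and Plac8 (-0.62). Ly6c2 was at 2.68 ± 1.51 against 8.57 ± 5.27 CPM. The disease-associated microglia list had 16 of 20 lower (median -0.30; camera adjusted p = 3.2e-05, adjusted p = 0.571 with an estimated correlation). Members included Gpnmb (-2.15), Spp1 (-1.22), Lpl (-0.93) and Lgals3 (-1.18). LXR targets had 8 of 10 lower (median -0.29; camera adjusted p = 0.0139, adjusted p = 0.168 with an estimated correlation), 1 of them past the threshold adjusted over the list alone. Members included Apoe (-1.21), Apoc1 (-1.94) and Scd2 (-0.50). Without vehicle replicate 2 the medians were -0.29 for monocyte-derived cell genes and -0.19 for disease-associated microglia genes. The LXR call ended without inhibitor replicate 6 (adjusted p = 0.0642) or vehicle replicate 2 (0.0609). Immediate early genes had 19 of 19 higher (median 0.31; camera adjusted p = 1.0e-05, adjusted p = 0.574 with an estimated correlation). Members included Dusp1 (0.56) and Fos (0.48).

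Homeostatic microglia genes, with 12 of 16 higher and a median of 0.10, did not pass (camera adjusted p = 0.0784), and Sall1 (0.19) and Cx3cr1 (0.19) were near 0. Without inhibitor replicate 2 or 4 or vehicle replicate 1 or 3 the list passed, at adjusted p = 0.0196, 0.0107, 0.00280 and 0.0143. It also passed in 3 of 6 other settings, without the filter (adjusted p = 0.0308), with detected genes (0.0289) and with sex (0.0278, added after the data were seen) as a covariate. Astrocyte genes had 7 of 9 lower (median -0.41; camera adjusted p = 0.00588, adjusted p = 0.571 with an estimated correlation), neuron genes 5 of 5 lower (median -0.83; camera adjusted p = 0.0118, adjusted p = 0.483 with an estimated correlation). Phagocytosis genes had 16 of 22 lower (median -0.08; camera adjusted p = 0.0118, adjusted p = 0.571 with an estimated correlation), 1 past the threshold adjusted over the list alone, and oxidative phosphorylation genes 13 of 16 lower (median -0.09; camera adjusted p = 0.0206, adjusted p = 0.819 with an estimated correlation). With 1 library left out the phagocytosis and oxidative phosphorylation calls held in 7 of 11 fits each (medians from -0.11 to -0.03 and from -0.13 to -0.004) and the astrocyte and neuron calls in 10. Without vehicle replicate 3 both of these ended (adjusted p = 0.0529 and 0.157), the neuron median at -0.25, and the astrocyte median was -0.80 without inhibitor replicate 1. The immediate early median was 0.48 without inhibitor replicate 5, and the LXR median ran from -0.30 to -0.18 in other settings. In 6 other settings of the fit phagocytosis and LXR targets held in 5 each and oxidative phosphorylation in 4. Of the genes with the smallest p, Cnnm3 (0.33), Mras (0.43) and Zfp691 (0.35) were higher and Sh3bgrl (-0.94) and Bcl2l1 (-0.45) lower, and the fatty acid transporter gene Cd36 was at 27.0 ± 8.42 against 95 ± 49.6 CPM. In total 0 of 12226 genes were called by edgeR and 671 had an unadjusted p under 0.05, where 611 are due by chance. DESeq2 called 11, limma-voom 0 and limma-trend on log2 FPKM 0, and edgeR called 7 without inhibitor replicate 4. In simulated data with this spread 84% of genes changed by 1 log2 unit were recovered. Median and test differed in sign in 3 lists, all uncalled, and the remaining camera adjusted p ran from 0.0784 to 0.812. Of 12 exact permutation tests of library measures between inhibitor and vehicle (two-sided), the lowest p was 0.0216. It belonged to the mitochondrial share of resting microglia (1.30% against 1.68%). The lowest Benjamini-Hochberg value of these exact tests was 0.260.

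**Figure D4:**
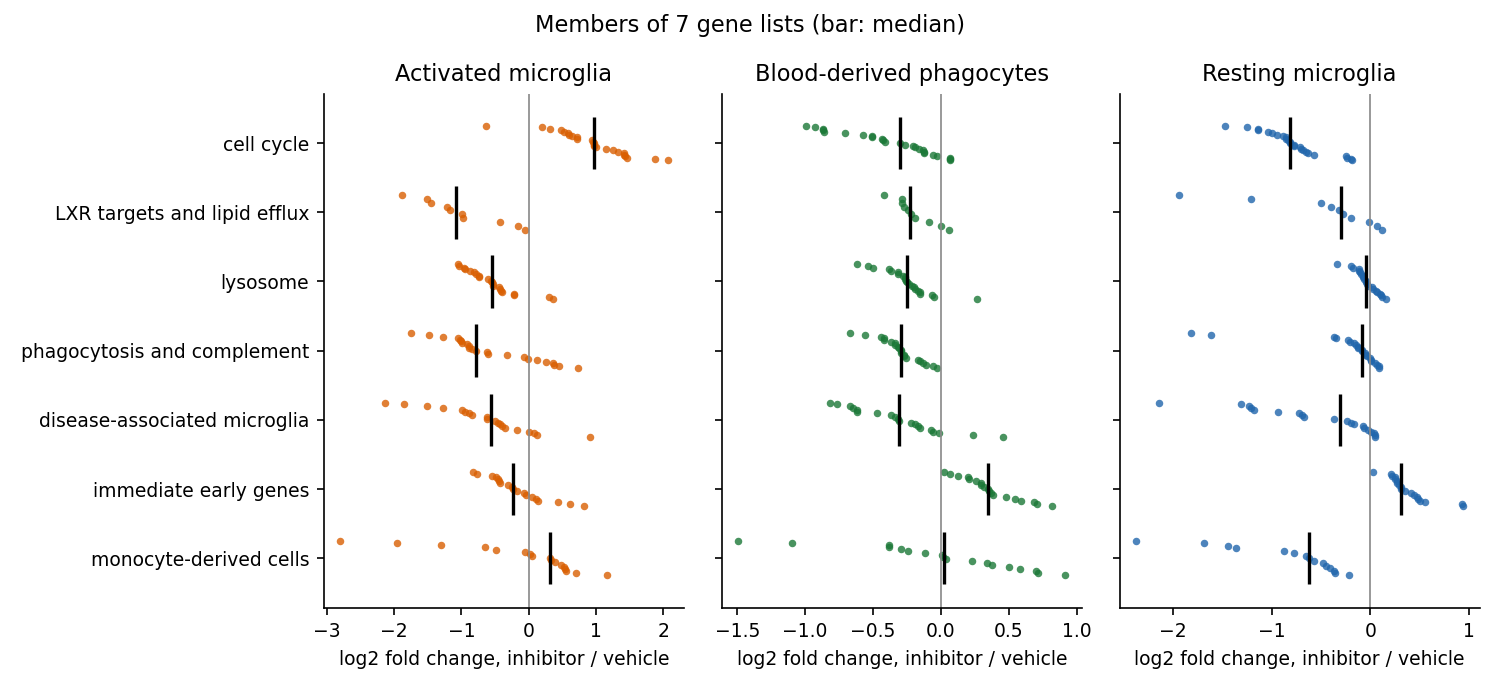
Log2 fold change, inhibitor against vehicle, of the members of 7 gene lists, each point 1 gene and each bar the list median, in the 3 populations; axis ranges differ between panels. All 25 cell cycle genes lie below 0 in resting microglia (median -0.81) and 24 of 25 above 0 in activated microglia (median 0.97).

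Whether the inhibitor effect itself differed between populations was tested as an interaction of 4 groups. With activated microglia, a changed mix of cells in the gate would enter the interaction as well. Beyond the neutrophil marker covariate, this was not tested. Cell cycle genes had the smallest camera p in both interactions with activated microglia. Their difference in inhibitor effect between activated and resting microglia had 24 of 25 higher (median 1.77; camera adjusted p = 9.1e-22, adjusted p = 0.0742 with an estimated correlation). Adjusted over the list alone 12 were past the threshold, and fry gave adjusted p = 0.0471. Members included Birc5 (2.20), Rrm2 (1.95), Tpx2 (2.27) and Tyms (1.96). Between activated microglia and blood-derived phagocytes the list had 24 of 25 higher (median 1.24; camera adjusted p = 2.1e-11, adjusted p = 0.228 with an estimated correlation). Members included Birc5 (2.26) and Top2a (1.47). LXR targets were more negative in activated microglia than in blood-derived phagocytes (9 of 10 lower, median -0.74; camera adjusted p = 0.00163, adjusted p = 0.228 with an estimated correlation), as in Apoe (-1.28) and Abca1 (-0.96). They were also more negative than in resting microglia (8 of 10 lower, median -0.61; camera adjusted p = 0.00228, adjusted p = 0.120 with an estimated correlation), as in Abca1 (-1.17) and Abcg1 (-0.82). Lysosome genes were also more negative in activated than in resting microglia (20 of 22 lower, median -0.56; camera adjusted p = 2.4e-07, adjusted p = 0.578 with an estimated correlation), as in Npc2 (-0.91) and Ctsa (-0.70). Immediate early genes were more negative in activated microglia than in blood-derived phagocytes (16 of 19 lower, median -0.58; camera adjusted p = 7.2e-07, adjusted p = 0.492 with an estimated correlation; 2 adjusted over the list alone), as in Egr1 (-1.25), Egr3 (-1.01) and Jun (-0.65). Monocyte-derived cell genes were more positive in blood-derived phagocytes than in resting microglia (18 of 18 higher, median 0.98; camera adjusted p = 1.0e-07, adjusted p = 0.214 with an estimated correlation), 5 of them adjusted over the list alone, as in Plac8 (1.33), S100a6 (1.43), Ms4a4c (0.88) and Hp (2.03). The interactions of Csf1r were -0.56, -0.75 and -0.17 for activated against blood-derived, activated against resting and blood-derived against resting cells.

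Of the other lists, 5 passed between activated microglia and blood-derived phagocytes (camera adjusted p between 2.6e-04 and 0.0415, adjusted p between 0.371 and 0.729 with an estimated correlation): interferon response with median 0.42, lysosome -0.32, border-associated macrophages -1.04, MHC class II -0.72 and inflammatory mediators -0.44. Between activated and resting microglia 5 more passed (camera adjusted p between 9.9e-05 and 0.0234, adjusted p between 0.578 and 0.757 with an estimated correlation): monocyte-derived cells 0.79, immediate early genes -0.63, neutrophils 1.84, interferon response 0.43 and inflammatory mediators -0.36. Between blood-derived phagocytes and resting microglia 4 more passed (camera adjusted p between 2.0e-05 and 0.0364, adjusted p = 0.657 with an estimated correlation): lysosome -0.21, cell cycle 0.44, MHC class II 0.46 and neutrophils 1.87. Adjusted over the list alone 2 MHC class II genes in the first and 2 monocyte-derived cell genes in the second were past the threshold. With 1 library left out, the calls of the first held in 13 of 22 fits for border-associated macrophages, 17 for interferon response and 18 for lysosome genes. In the second they held in 16 for inflammatory mediators, 19 for interferon response and 20 for neutrophils, and in the third in 12 for neutrophils and 19 for MHC class II. Every other call in the 3 interactions held in all 22. Medians in these fits ran from -0.53 to -0.19 for lysosome and 0.20 to 0.64 for interferon genes in the first. They ran from -0.62 to -0.04 for inflammatory mediators, 0.97 to 2.27 for neutrophils and 0.19 to 0.53 for interferon genes in the second. In the third the ranges were 1.04 to 2.54 for neutrophils and 0.19 to 0.63 for MHC class II. The third monocyte-derived median was 0.48 without vehicle resting microglia replicate 2, and the third cell cycle median 0.72 without inhibitor resting microglia replicate 4. In other settings of the fit, border-associated macrophages held in 6 of 8, interferon response in 7 of 8 in both, and neutrophils in 6 of 7 and 5 of 6, their own level as a covariate left aside. The first LXR median ran there from -0.88 to -0.49 and the second inflammatory median from -0.81 to -0.31. NK cell genes in the second missed the threshold (median 2.34, camera adjusted p = 0.0515), passing in 11 of 22 fits with 1 library left out and in 4 of 8 other settings. The lists that did not pass had camera adjusted p from 0.0934 to 0.864, 0.0515 to 0.997 and 0.0741 to 0.992 in the 3 interactions.

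No single gene passed an interaction. Between activated microglia and blood-derived phagocytes edgeR called 0 of 12568 genes, with 682 at an unadjusted p under 0.05, DESeq2 32, and limma-voom and limma-trend on log2 FPKM 0 each; 5 were called without inhibitor activated microglia replicate 6. Between activated and resting microglia edgeR called 0 of 13172, with 774 unadjusted, DESeq2 51 and the limma tests 0; 1 was called without inhibitor activated microglia replicate 3 or 6 or vehicle activated microglia replicate 4. Between blood-derived phagocytes and resting microglia edgeR called 0 of 12921, with 891 unadjusted, DESeq2 13 and the limma tests 0; 1 was called without vehicle blood-derived phagocytes replicate 4 or 5. The smallest p belonged to Creb5 (-2.96), Egr1 (-1.25), Zdhhc18 (0.87) and Saa3 (-2.30) in the first, Ly6c2 (2.37), Cd302 (-1.48) and Pid1 (-1.23) in the second and Kcna3 (1.02), Map2 (2.32) and Mmaa (-1.21) in the third, beside genes with fewer than 4 counts in a group, for which no fold is given.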

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

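The tests of explanations in this part were chosen after the results were seen, except that the prediction for the T and NK marker covariate was written before its result. In 150 sets of values within a group, Dixon's test at the 5% level picked out 7 with a library far from the others, where 7.5 are due by chance. The gap statistic was 0.650 for Ccr2 in inhibitor activated microglia, 0.766 for the inflammatory mediator score in vehicle activated microglia, and 0.827 for the same score in vehicle resting microglia. In inhibitor blood-derived phagocytes it was 0.634 for the share of counts in the 100 most abundant genes, 0.651 for Ptprc and 0.694 for the score of CSF receptors and myeloid regulators. The glycolysis score of vehicle blood-derived phagocytes gave 0.715. No library was left out for these.

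Lists whose inhibitor effect differed between populations by camera were looked at because the populations came from the same model. Between activated microglia and blood-derived phagocytes the median differences were 1.24 for cell cycle genes, -0.58 for immediate early genes and -0.74 for LXR targets. Between activated and resting microglia they were 1.77 for cell cycle genes, -0.61 for LXR targets and -0.56 for lysosome genes, and between blood-derived phagocytes and resting microglia 0.98 for monocyte-derived cell genes. None held with an estimated correlation. From data outside the count table came 36 genes called in blood-derived phagocytes and a Clec7a difference of 3.02 log2 FPKM between activated and resting microglia.

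The first pattern weighed was the high level of neutrophil, NK and T cell genes in the activated microglia gate. Cells of these types within the gate would raise all genes of a type together. Across the 11 activated microglia libraries the neutrophil genes had a median pairwise correlation of 0.867, above the highest value of 0.405 in random gene sets (permutation p = 0.001), and the NK genes 0.983, above 0.659 (permutation p = 0.001), which is consistent with these cells in the gate. The T cell genes had 0.372, below the highest random value of 0.430 (permutation p = 0.004). The random sets could hold genes at lower levels than the markers, so these permutation p-values may be too small. Most T cells lack CD11b, for which the gate was sorted, so the source of the T cell genes stays open. Sparse libraries were excluded as the source: the neutrophil median for activated against resting cells was 10.58 with the number of detected genes as a covariate and 9.98 without the sparsest libraries. Among 100 splits only 1, the real one, reached its number of called genes, and the highest other called 0, so chance is excluded. Expression of these genes by activated microglia themselves was not tested and stays open.

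The second pattern was the set of 32 genes in blood-derived phagocytes. With T and NK marker level as a covariate their median fold change in their own direction was 0.71 (quartiles 0.56 to 0.80) against 0.69 (0.59 to 0.82) before, and all 32 kept their sign. This argues against these cells as the source of the set as a whole but does not exclude them. The markers were scarce, with NK cell genes at 0.0128% of counts with inhibitor, and error in such a covariate would leave fold changes in place. Fold changes of single genes ran from 0.69 to 1.21 times their value before, and Traf1 went from 1.12 to 0.77, so a part in single genes stays open. The calls went to 0 with a smallest adjusted p of 0.0585, as standard errors grew by a median of 1.17 times, a degree of freedom was spent and some fold changes shrank. With the number of detected genes as a covariate the median was 0.71 and all 32 stayed called. Detected genes differed little between inhibitor and vehicle (13258 against 13381, exact permutation p = 0.537), so this covariate could hardly move the fold changes. The share of counts in the 100 most abundant genes (33.7% against 35.3%, exact permutation p = 0.0909) was not used as a covariate. Library complexity is therefore not excluded. A larger share of nuclear RNA may contribute: genes outside the protein-coding table, many of them non-coding, were higher with inhibitor by 0.239 relative to genes in it (exact permutation p = 0.00866), Malat1 rose, and Neat1, which the prediction also named, was higher by 0.70 ± 0.21 without passing (adjusted p = 0.108). Among 100 of 462 possible splits only the real one called as many genes, and the highest other called 29. This is under the limit of 5 of 100. Not all splits were tried and the highest other came close, so chance is not fully excluded. A direct response of the cells to the drug stays open, untested. So does a changed mix of cells in the gate, since dendritic cell genes were higher too and no dendritic cell covariate was run.

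The third pattern was the lower cell cycle list in resting microglia. Infiltrating cells with the mean profile of either other gate were argued against as the source. The share of activated-gate cells needed, a median of 108%, would bring 11738 CPM of S100a8, against 14.3 measured. In blood-derived phagocytes 23 of 25 genes were lower than in resting microglia. A dividing subset of infiltrating cells without neutrophil genes would escape this test, and monocyte-derived cell genes were also lower with inhibitor (median -0.62). Such a subset is therefore not excluded. A single library was excluded as the source, since the highest median with 1 library left out was -0.66. Of 100 splits 2 gave a camera p as small, the real one and another at 2.1e-38, in this permutation of labels. This is under a limit of 5 of 100 chosen after the result was seen, but another grouping of these libraries gave a smaller camera p for these genes. Fewer dividing microglia with inhibitor and an unlabelled difference between animals may therefore both contribute.

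The counts of the other comparisons were held against the same 100 splits. For blood-derived against activated cells 1 split reached the count, the highest other calling 0. Every split reaches a count of 0, so for the other comparisons genes at an unadjusted p under 0.05 were counted. For the inhibitor in activated microglia 21 splits had as many as the real 417 (highest other 1293) and in resting microglia 32 had as many as 671 (2362). For the interactions 15 had as many as 682 between activated and blood-derived (1472), 31 as many as 774 between activated and resting (1990) and 25 as many as 891 between blood-derived and resting cells (2204). Chance is not excluded for any of these 5. Other splits that call up to 420 genes point to structure among the libraries that treatment does not follow.

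The camera calls of lists were held against the same splits. Of 80 calls 27 had a p reached by fewer than 5 of 100 splits, the real one included, and for the other 53 chance is not excluded (5 to 49 splits). With the inhibitor in activated microglia these 27 include LXR targets (1 split), inflammatory mediators and lysosome genes (4 each), but not cell cycle and disease-associated microglia (5 each), NK cell (17), phagocytosis (19), T cell (29) or neutrophil genes (49). In blood-derived phagocytes they include phagocytosis (1) and lysosome genes (2), but not dendritic cell (5), disease-associated microglia (8), LXR target (11), immediate early (15), NK cell (21), T cell (41) or cell cycle genes (45). In resting microglia they include monocyte-derived cell (1), cell cycle (2) and LXR target genes (4), but not disease-associated microglia (23) or immediate early genes (24). For activated against resting cells 7 of 11 calls were under this limit, for blood-derived against activated cells 5 of 15, and for the interactions 3 of 8, 3 of 8 and 1 of 5. Cell cycle genes in both interactions of activated microglia had 1 split each.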

How the results depend on the processing

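The alternatives called added were chosen after the data were seen: sex, the 3 sparsest libraries, and the marker covariates. The sparse-library alternative fixed beforehand (0.7 times the median) was not run, as no library met it. The count for activated against resting microglia (3499) stayed within 1.5 times under every setting, from 2680 to 5103. Over all results and settings, 62 counts stayed within 1.5 times and 19 moved, and with 1 library left out 102 stayed and 17 moved. For genes under the naming rule 2773 values kept direction and call, 72 gained a call, 24 lost it and 9 changed sign (3564, 18, 44 and 11 with 1 library left out). For the lists chosen to be described at length 370 kept both, 90 lost and 3 gained the call and 3 changed direction (596, 13, 5 and 2). Most losses came with the estimated correlation and fry. Camera calls of lists mentioned only briefly are outside this tally. The cause was not tested for any change unless given.

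In blood-derived phagocytes the 32 calls became 342 with DESeq2, 142 with limma-voom, 133 with the authors' log2 FPKM, 106 with detected genes as a covariate, 61 with the replicate block, and 0 with all 33 libraries in 1 fit or with the T and NK covariate (added; larger standard errors and, for some genes, smaller fold changes are the cause). RLE gave 39, no filter 35 and sex (added) 26. The 133 with log2 FPKM include 36 genes outside the count table, all higher, so that setting changes the genes tested as well as the method. With 1 library left out the counts ran from 0 to 181, the moved ones being 0, 2, 2, 3, 8, 10, 16, 19 and 181. In the 1-fit setting the spread of activated microglia enters the shared dispersion, and the same setting raised the activated microglia count from 0 to 322; DESeq2 called 1 there. In resting microglia DESeq2 called 11, and 7 were called without inhibitor replicate 4.

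For blood-derived against activated cells the 2176 calls became 3307 with detected genes as a covariate, 1401 with the replicate block, and 3619 without the sparsest libraries (added), the same fit as without vehicle activated microglia replicate 2. With 1 library left out they ran from 1650 to 3619. For activated against blood-derived effects the interaction count of 0 became 32 with DESeq2, 4 with all libraries, 1 with the replicate block and 5 without inhibitor activated microglia replicate 6. For activated against resting effects it became 51 with DESeq2, 1 with all libraries, and 1 without 1 of 3 libraries. For blood-derived against resting effects it became 13 with DESeq2 and 1 without 1 of 2 libraries. Replicate numbers did not pair libraries of an animal: in 33 same-number pairs the mean correlation was -0.0023 against 0.0005 for other numbers (permutation p = 0.537), and 16 of those pairs were unlike in Y-linked transcripts, so the replicate block is no paired analysis.

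Of results that had passed, only the T cell list in blood-derived phagocytes changed sign (adjusted p = 0.305 with the T and NK covariate, by its construction), and with it Cd3d became -0.12 there. In resting microglia Ptprc, at -0.04, ran from -0.118 to 0.0146 with 1 library left out. Itgam there, at -0.00317, was 0.000516 without the filter, 0.0125 with all libraries, 0.00184 with log2 FPKM and 0.0362 with detected genes as a covariate, and ran from -0.0517 to 0.0424 with 1 library left out. The inflammatory list for activated against resting microglia had adjusted p = 0.790 with detected genes as a covariate, 0.957 without the sparsest libraries, and 0.233 to 0.992 with 1 library left out. The interaction of Ccr2 between activated and resting microglia was -0.68 with log2 FPKM, -0.11 with detected genes, -0.10 with the replicate block, -0.75 with neutrophil level (added), and from -0.42 to 0.66 with 1 library left out.

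With detected genes as a covariate the split of activated against resting microglia moved from 2205 higher and 1294 lower to 2281 and 718, and the median of all genes by 0.56. Whether depth limited the counts was not tested. The spread of activated microglia limited theirs, with 3% of simulated changes of 1 log2 unit recovered.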

Other observations

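Values in the log2 FPKM table for genes outside the count table, chosen after they were seen, add non-coding RNAs to the inhibitor comparison in blood-derived phagocytes. Of 635 such genes tested with limma-trend 36 were called, all higher, and 188 had an unadjusted p under 0.05. Malat1, a nuclear RNA, rose from 9.15 ± 0.37 to 10.01 ± 0.37 log2 FPKM (0.86 ± 0.19, adjusted p = 0.0453). The small nucleolar RNA hosts Gas5 and Snhg15 rose by 0.59 (adjusted p = 0.0352) and 0.84 (adjusted p = 0.0317). The interaction of Malat1 between blood-derived phagocytes and resting microglia was 0.90 (adjusted p = 0.630). In activated microglia limma-trend called 0 of 993 such genes, with 47 at an unadjusted p under 0.05, and in resting microglia 0 of 896, with 32.

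Clec7a, the beta-glucan receptor gene of disease-associated microglia, was absent from the count table and stood at 8.33 ± 0.31 log2 FPKM in vehicle activated against 5.32 ± 0.67 in resting microglia (3.02 ± 0.28, limma-trend adjusted p = 3.5e-06). The interferon-induced gene Mx2 differed by -1.59 (adjusted p = 0.0114). Between blood-derived phagocytes and activated microglia, Neat1 differed by -3.06 and Malat1 by -2.18. Genes outside the count table were called in 302 of 896 cases for activated against resting microglia (187 higher, 115 lower) and in 279 of 674 for blood-derived against activated cells (55 higher, 224 lower). The 3 interactions had 0 calls by limma-trend, with 126, 61 and 128 genes at an unadjusted p under 0.05.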
